A study of Mus musculus with 21 samples.

How the data were processed

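Gene expression was measured by RNA sequencing in 21 mouse libraries, 3 for each of 7 groups formed by 2 cell lines and 4 stages of pluripotency, of which the EpiSC stage was sampled in A2 only. Per the labels' protocols, total RNA was isolated with a column kit that included DNase treatment, and libraries were made with an Illumina TruSeq RNA kit whose chemistry does not mark the strand. The values used are counts: the authors deposited 1 table of raw read counts per Ensembl gene and library. Per the submitters' processing notes, HISAT2, SAMtools and featureCounts were used with the mouse build GRCm38. The versions, the settings, the annotation and the strand setting are not given in the sources used here. The table was tested and held whole numbers with a different total in each library. All 39396 gene identifiers matched GENCODE release M21 on GRCm38, from which coordinates were taken. Symbols were those of the deposited table, where they were missing for 53 identifiers and shared by 31. No column of values per sample was left unused.

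Total counts ranged from 15320599 to 23490527 per library. Of the genes, 11356 had no count in any library. The filter filterByExpr, with the 7 groups, a minimum count of 10 and a minimum total of 15, kept 16575 genes, which held at least 99.89% of the counts of each library. Counts were scaled with TMM factors, which were between 1.136 and 1.145 in EpiSC libraries and between 0.9326 and 1.007 in the others. A single quasi-likelihood model (edgeR 4.0.16 with R 4.3.3) was fitted to all 21 libraries with 1 mean per group, so that every comparison used the same estimate of spread. The comparisons were naive against ground, EPL against ground and EPL against naive, each as the mean of the A2 and D3 differences, EpiSC against EPL, ground and naive within A2, D3 against A2 as the mean over 3 stages, and the interaction of line and stage. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Each group had libraries numbered 1 to 3 per the labels. Whether these came from separate cultures is not given in the sources used here. The series' own description calls the samples paired without saying how. No pairing was modelled, which bears on every p-value, and every library was used.

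Gene lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The 28 lists cover pluripotency factors of each stage, signalling responses, amino acid and proline metabolism, DNA methylation, lineage and germline markers, fibroblast markers, central metabolism, imprinted genes, and Y-linked and X-inactivation genes. Some lists share members, so their calls are not independent. The epithelial-mesenchymal transition list holds both epithelial and mesenchymal genes, so its call gives no direction of the transition. Klf4, Klf5, Tfcp2l1, Stat3 and Gbx2 are in both the naive and the LIF lists, and T and Eomes in both the primed and the mesendoderm lists. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, in both directions, adjusted over the lists of a comparison, and again with an estimated correlation. Camera compares the genes of a list with all other genes. Within a list the counts of higher and lower genes use the p-values adjusted over all genes, and a second count uses p-values adjusted over the list alone. The genes named for a comparison were the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries within each line compared. Gene models with names of clones or predictions were left out of this part. The plan also left out ribosomal and mitochondrial pseudogenes. The filter as run left out every pseudogene with a name ending in -ps, with or without a number. Up to 4 called members of each list described were added, as were Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Tfcp2l1, Fgf5, Otx2, Dnmt3b, Pou3f1 and T in every comparison, and the imprinted, Y-linked and X-inactivation genes in the comparison of lines. Some genes that meet this rule are not reported here, and the counts of named genes leave them out.

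Levels are CPM, counts scaled to the TMM library size, with their SD over the libraries of a group, and log2 differences are given with a standard error from the fitted value and its F statistic. A fold against a group without counts was computed against 3 counts over the group, and with 1 to 3 counts it is given as a ratio with its 95% Poisson interval. Each library was placed on the axis from the A2 ground mean to the A2 EpiSC mean by projecting log2 CPM (prior count 2) over the genes called between these groups, and positions were compared with exact two-sided permutation tests. Alternatives were size factors by RLE, scaling to the total count, no filter on low counts, a stricter filter of 1 CPM and 10 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a fold change of 1.5, each line alone, the libraries of the compared groups alone, a replicate block, fry for the lists, a prior count of 0.5 or all genes for the axis, and leaving out each library in turn. Leaving out the EpiSC libraries, and leaving out genes over 10-fold higher in EpiSC, were added after the data had been seen.

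The procedure was tested on simulated data with the groups, depths and spread of these libraries, with 200 genes changed per comparison. For changes of 1.5-, 2- and 4-fold it recovered 76.1%, 94% and 98.5% in naive against ground, 88.1%, 97% and 98.5% in EPL against ground, and 92.5%, 94% and 98.5% in EPL against naive. It recovered 74.6%, 89.6% and 98.5% in EpiSC against EPL, 68.7%, 85.1% and 100% in EpiSC against ground, 64.2%, 91% and 100% in EpiSC against naive, 85.1%, 97% and 100% in D3 against A2, and 49.3%, 76.1% and 93.9% in the interaction. Between 7 and 15 unchanged genes were called per comparison, of 16231 to 16397 tested. The changed genes were drawn from those with a mean above 1 CPM, so the recovery does not cover lower genes. All other genes were set equal between the compared groups. In the data 40.7% to 73.2% of genes were called per comparison and 17% in the interaction. The numbers of false calls therefore do not carry over to the data, nor do the runs test scaling when most genes change. For EPL against naive, 0 of 28 lists were called by camera when no list was changed. A list raised 1.5-fold was the 1 list called when it alone was changed. Genes were simulated independently of each other, so these runs cannot judge list calls among correlated genes. A simulated position of 0.3 on the axis was found as 0.303.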

Results

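RNA sequencing measured gene expression in 21 libraries of mouse pluripotent cells, 3 from each of 7 combinations of cell line and stage. Ground-state embryonic stem cells (mESCs) of the lines A2 and D3 grew in serum with 1000 U/mL of leukaemia inhibitory factor (LIF), a cytokine that signals through STAT3, together with inhibitors of the kinases MEK and GSK3. Naive mESCs were the same cells 4 days after the inhibitors had been withdrawn. Early primitive ectoderm-like (EPL) cells came from ground-state cells kept for 4 days with 330 U/mL LIF and 400 uM L-proline, in a medium listed without the inhibitors. Epiblast stem cells (EpiSCs) were present for A2 alone. Per the labels' protocols they were isolated after A2 cells had been implanted in a pseudopregnant mouse, and they were kept with activin A and basic fibroblast growth factor. The series places these 4 stages along a continuum of pluripotency, and the comparisons ask which genes differ at each step and whether both lines take the steps alike.

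Total counts per library ranged from 15320599 to 23490527. Within A2 the range was 18824044 to 22286752 in ground, 17306036 to 20468946 in naive, 16600682 to 18115933 in EPL and 19171874 to 22517799 in EpiSC libraries. In D3 it was 19599380 to 22246738 in ground, 17743542 to 18683783 in naive and 15320599 to 23490527 in EPL libraries. Of 39396 genes in the table, 28040 had a count in at least 1 library and 16575 were tested. Levels below are counts scaled to the TMM library size (CPM), as mean ± SD with n = 3 libraries per group, and changes are log2 fold changes ± SE. Counts within a gene list were the same adjusted over the list alone, except where both are given. A gene with no count in a group was bounded at 3 counts over the group, and such bounds and intervals cover counting error only. It is not stated whether the 3 replicates of a group were separate cultures, so p-values measure the spread between these samples. The first principal component of log2 CPM carried 45.3% of the variance, with scores from -83.5 in a D3 ground library to 139.9 in an A2 EpiSC library, and the second 28.8%. Mitochondrially encoded transcripts took between 1.53 ± 0.36% of counts in D3 EPL and 2.65 ± 0.15% in A2 EpiSC.

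**Figure D1:**
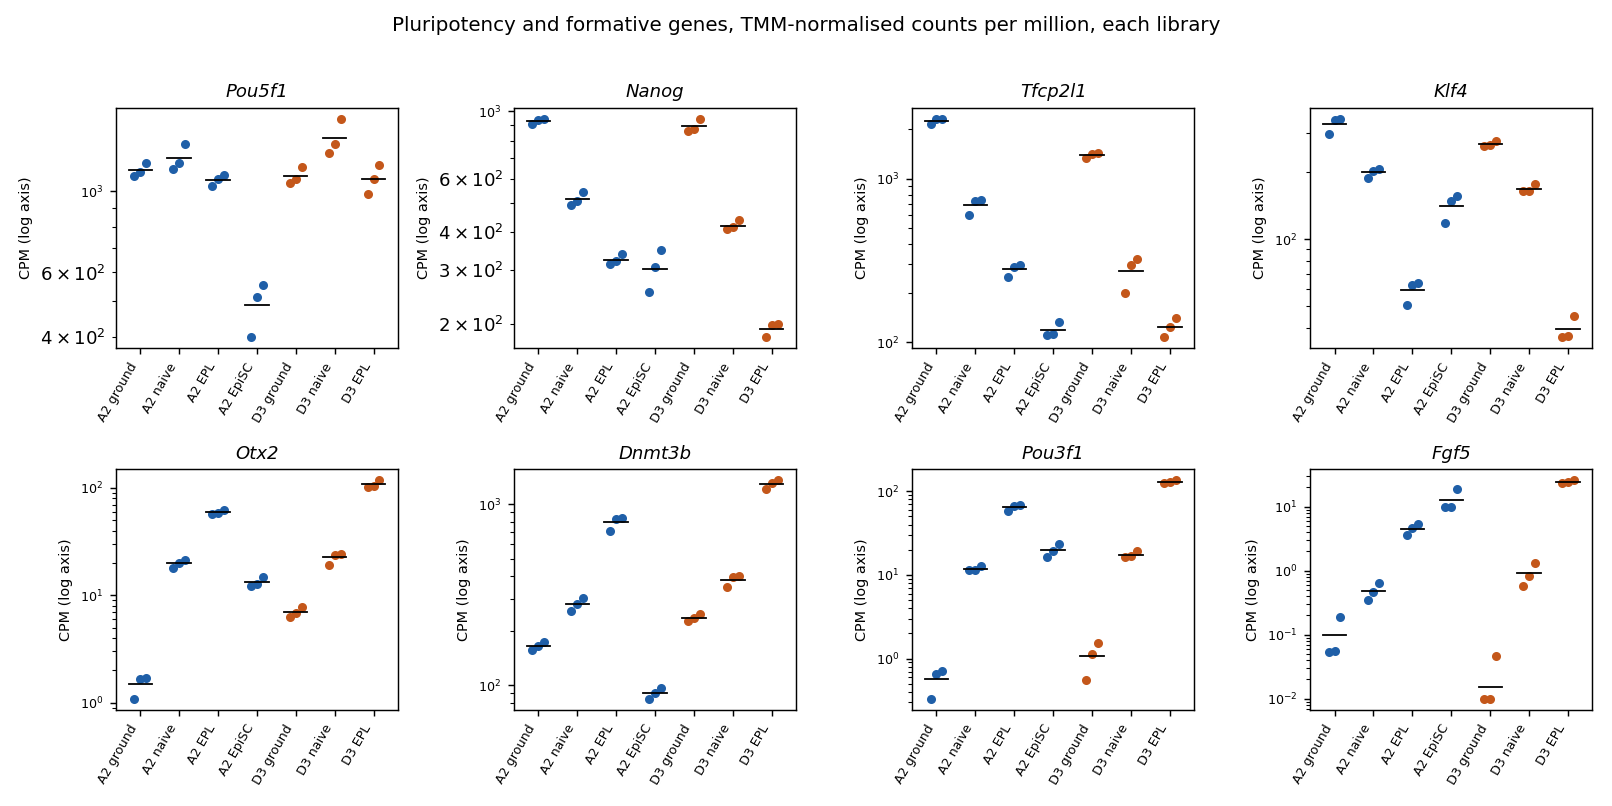
CPM (log axis) of Pou5f1, Nanog, Tfcp2l1, Klf4, Otx2, Dnmt3b, Pou3f1 and Fgf5 in the 4 stages, with A2 in blue and D3 in orange, 1 point per library and a line at each mean of 3. Pou5f1 lay at 1142 CPM in A2 ground and 489 CPM in A2 EpiSC, while Otx2 was 1.48 CPM in A2 ground, 59.2 CPM in A2 EPL and 13.2 CPM in A2 EpiSC.

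At the step from ground to naive, the withdrawal of the inhibitors, genes that respond to ERK signalling and genes of the formative epiblast rose, and 11 of 18 targets of Wnt signalling fell. Egr1, an immediate early transcription factor induced by ERK, rose from 0.637 ± 0.22 to 58.6 ± 3.9 CPM in A2 and from 0.751 ± 0.21 to 57.1 ± 5.5 CPM in D3 (log2 change 6.36 ± 0.19, edgeR adjusted p = 1.17e-17). Dnmt3a, a de novo DNA methyltransferase, rose 7.08-fold (adjusted p = 1.11e-20), and Axin2, a feedback inhibitor of Wnt signalling, fell by 3.12 ± 0.11 on the log2 scale (adjusted p = 2.25e-16). Otx2, a homeobox factor of the postimplantation epiblast (ENSMUSG00000021848, GRCm38 chromosome 14, 48657677 to 48673819), rose by 2.72 ± 0.10. Tfcp2l1, a factor downstream of LIF and STAT3 (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168), fell by 2.03 ± 0.10.

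Among the genes with the steepest rises were Myrf (6.13 ± 0.11), the Notch ligand Dll1 (5.96 ± 0.20) and the paired-box factor Pax8 (5.83 ± 0.27). The epithelial splicing regulator Esrp1 rose by 5.73 ± 0.11, Spink1 by 5.70 ± 0.29, the cyclin Ccnd2 by 5.64 ± 0.23 and Foxp1 by 5.62 ± 0.11. Among the steepest falls, Dmgdh, which oxidises dimethylglycine, changed from 54.4 ± 5.3 to 0.333 ± 0.11 CPM in A2 and from 60.8 ± 6.7 to 0.113 ± 0.058 CPM in D3. The homocysteine methyltransferases Bhmt2 and Bhmt fell by 7.24 ± 0.19 and 6.41 ± 0.25. Falls of similar size were measured for the aldehyde oxidase Aox3 (-7.22 ± 0.24), Crxos (-6.98 ± 0.11), the cation channel Trpm1 (-6.94 ± 0.17), the homeobox gene Nkx1-2 (-6.79 ± 0.22) and Ly6a (-6.46 ± 0.13).

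Of 14 primitive ectoderm and formative genes, 13 rose, 0 fell and 1 was not called, with a median log2 change of 2.77 (camera adjusted p = 3.92e-20). Pou3f1 rose by 4.22 ± 0.16, Grhl2 by 3.64 ± 0.08, Sox11 by 3.49 ± 0.12, Fgf15 by 4.58 ± 0.16 and Dnmt3b by 0.73 ± 0.06. Fgf5 was called (adjusted p = 1.1e-05), although it reached only 0.911 ± 0.39 CPM in D3 naive, 54.2 times D3 ground with a counting interval of 9.73 to 2140. Of 17 ERK-responsive genes 15 rose and 0 fell (median 1.30, camera adjusted p = 1.98e-15). They included Dusp6, which inactivates ERK (1.86 ± 0.05), the feedback inhibitor Spry4 (2.97 ± 0.08) and Myc (2.50 ± 0.07). These were the lists whose call held with an estimated correlation, at adjusted p = 6.43e-06 and 0.00067.

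Naive pluripotency factors were split, with 4 higher, 12 lower and 4 not called among 20 (median -0.35, camera adjusted p = 0.0336, adjusted p = 0.475 with an estimated correlation). Tbx3 fell by 1.16 ± 0.05, Klf4 by 0.69 ± 0.07, Esrrb by 0.49 ± 0.08 and Pecam1 by 0.86 ± 0.05, while Gbx2 rose by 1.47 ± 0.10. Zfp42 was not called (0.01 ± 0.06, adjusted p = 0.857). In the general pluripotency list 8 of 15 genes rose and 2 fell (median 0.16, camera adjusted p = 0.00383, adjusted p = 0.45 with an estimated correlation). Lin28a, which blocks processing of let-7, rose by 2.29 ± 0.06, Utf1 by 1.82 ± 0.10, Dppa4 by 1.45 ± 0.06 and Dppa2 by 1.29 ± 0.05, whereas Nanog fell by 0.97 ± 0.06. Pou5f1 and Sox2 rose by 0.23 ± 0.07 and 0.16 ± 0.05, and the call of Pou5f1 was lost in A2 alone (0.10, adjusted p = 0.402) and that of Sox2 in D3 alone (0.13).

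Of 18 Wnt target genes 5 rose and 11 fell, or 6 and 11 adjusted over the list alone (median -0.46, camera adjusted p = 0.0336, adjusted p = 0.475 with an estimated correlation). The homeobox gene Cdx1 fell by 4.75 ± 0.18, Tnfrsf19 by 2.08 ± 0.09 and T by 1.83 ± 0.26, and Bmp4 rose by 1.56 ± 0.06. Among 12 genes of the DNA methylation machinery 7 rose and 5 fell (median 0.39, camera adjusted p = 0.00372, adjusted p = 0.283 with an estimated correlation). Dnmt3l, the cofactor of the de novo enzymes, rose 6.04-fold, and Uhrf1, which recruits the maintenance methyltransferase, fell by 0.77 ± 0.06. Imprinted genes mostly rose, 19 of 25 with 4 lower (median 0.97, camera adjusted p = 4.16e-07, adjusted p = 0.0876 with an estimated correlation). Cdkn1c, a cyclin-dependent kinase inhibitor, rose by 5.15 ± 0.10, Phlda2 by 3.64 ± 0.14 and Snrpn by 1.52 ± 0.07, while Plagl1 fell by 4.64 ± 0.17.

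Primitive endoderm markers rose in 14 of 19 cases and fell in 2 (median 1.55, camera adjusted p = 0.00573, adjusted p = 0.417 with an estimated correlation). Among them were Lamb1 (1.95 ± 0.11), Sox7 (3.15 ± 0.25) and Col4a1 (2.01 ± 0.16). Neurectoderm markers rose in 6 and fell in 3 of 13 cases, or 8 and 3 adjusted over the list alone (median 0.58, camera adjusted p = 0.00927, adjusted p = 0.192 with an estimated correlation). Pax6 rose by 5.04 ± 0.23 and Neurod1 by 3.34 ± 0.12, while Sox21 fell by 2.43 ± 0.11. Of 12 genes expressed in 2-cell-like cells 10 rose and 0 fell (median 1.73, camera adjusted p = 0.00939, adjusted p = 0.475 with an estimated correlation). Zscan4d and Zscan4c rose by 2.43 ± 0.21 and 2.68 ± 0.23, and reads of these paralogs cannot be assigned with certainty. Across the genome 10518 of 16575 genes were called, 5246 higher and 5272 lower in naive cells, and 3464 of them changed at least 2-fold, 2184 higher and 1280 lower. With total-count scaling 5973 were higher and 4594 lower.

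**Figure D2:**
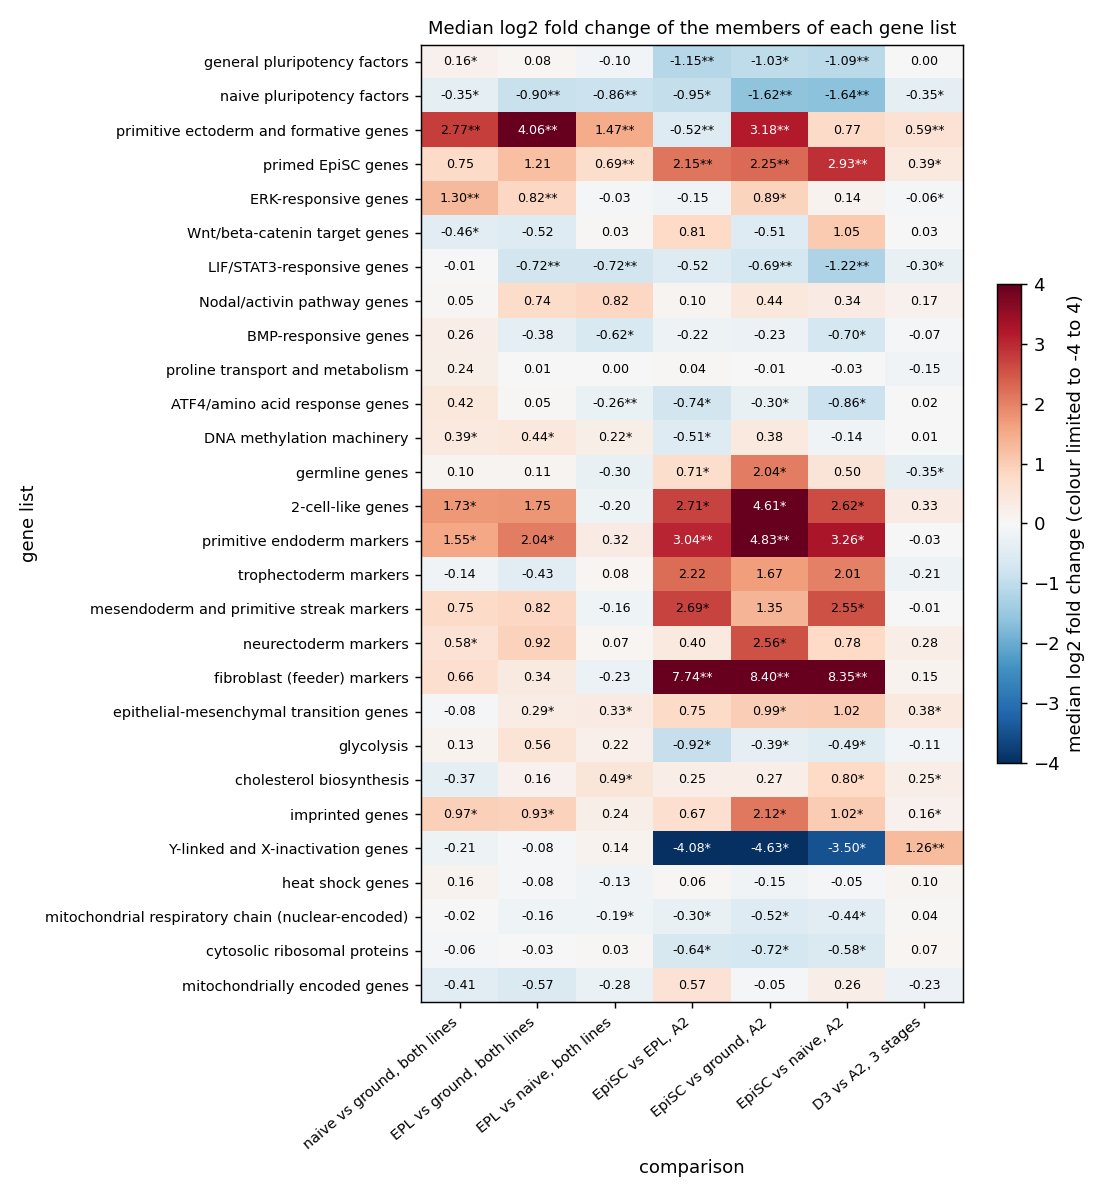
Median log2 change (colour, limited to -4 to 4) of each of the 28 gene lists in each comparison, with 1 asterisk where the list was called with the preset correlation and 2 where the call held with an estimated one. Formative genes had medians of 2.77 in naive and 4.06 in EPL cells against ground state, and fibroblast markers 7.74 in EpiSC against EPL.

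In EPL cells, made from ground-state cells with proline and less LIF, all 14 formative genes rose over ground state (median 4.06, camera adjusted p = 1.17e-39), a call that held with an estimated correlation (adjusted p = 7.18e-08). Pou3f1 rose from 0.567 ± 0.21 to 64.6 ± 5.3 CPM in A2 and from 1.08 ± 0.49 to 130 ± 5.3 CPM in D3 (6.89 ± 0.14, edgeR adjusted p = 7.73e-21). Otx2 rose by 4.64 ± 0.09, Grhl2 by 3.94 ± 0.08, Dnmt3a by 3.59 ± 0.06 and Dnmt3b by 2.36 ± 0.06. Fgf5, an epiblast growth factor (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030), reached 24.4 ± 1.2 CPM in D3 EPL, 1450 times D3 ground with a counting interval of 260 to 57300. In A2 it was at 4.51 ± 0.85 CPM in EPL and 0.0996 ± 0.078 CPM in ground.

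Naive pluripotency factors fell in 18 of 20 cases and rose in 1 (median -0.90, camera adjusted p = 3.49e-16). LIF- and STAT3-responsive genes, which share members such as Klf4 and Tfcp2l1 with that list, fell in 11 of 15 and rose in 3 (median -0.72, camera adjusted p = 8.78e-07). Both calls held with an estimated correlation, at adjusted p = 0.00376 and 0.013. So did that of the ERK-responsive genes, of which 14 of 17 rose and 1 fell (median 0.82, camera adjusted p = 4.27e-11, adjusted p = 0.00286 with an estimated correlation). Tbx3 fell by 3.84 ± 0.06, Tfcp2l1 by 3.26 ± 0.10, Klf4 by 2.62 ± 0.08, Spp1 by 2.10 ± 0.05, Pecam1 by 1.82 ± 0.05, Esrrb by 1.33 ± 0.08 and Zfp42 by 0.67 ± 0.06. Bcl3, a LIF-responsive gene, fell by 1.15 ± 0.06. Rises among the ERK-responsive genes included Egr1 (5.82 ± 0.20), Spry4 (3.50 ± 0.08), Myc (2.54 ± 0.07) and Dusp6 (2.40 ± 0.05).

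General pluripotency factors as a list were not called (5 higher and 4 lower of 15, median 0.08, camera adjusted p = 0.116). Nanog fell by 1.86 ± 0.06, while Pou5f1 (-0.06 ± 0.07, adjusted p = 0.51) and Sox2 (-0.03 ± 0.05, adjusted p = 0.575) were not called, and with total-count scaling both values were above 0. Sox2 was called lower in D3 alone (-0.19, edgeR adjusted p = 0.0203) and not in A2 alone (0.12, adjusted p = 0.197). Epithelial-mesenchymal transition genes had 9 higher and 6 lower of 17 (median 0.29, camera adjusted p = 0.0228, adjusted p = 0.139 with an estimated correlation). Esrp1 rose by 7.22 ± 0.10, the adhesion molecule Epcam by 2.55 ± 0.07 and the tight junction gene Cldn7 by 3.57 ± 0.18, and the mesenchymal factor Zeb1 fell by 1.24 ± 0.09. In the DNA methylation list 6 of 12 rose and 4 fell (median 0.43, camera adjusted p = 2.96e-05, adjusted p = 0.0864 with an estimated correlation), including Dnmt3l (2.88 ± 0.07) and Uhrf2 (0.78 ± 0.05).

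Imprinted genes rose in 19 of 25 cases and fell in 3 (median 0.93, camera adjusted p = 4.11e-07, adjusted p = 0.0534 with an estimated correlation). Cdkn1c rose by 5.18 ± 0.10, Phlda2 by 3.88 ± 0.14 and Snrpn by 2.21 ± 0.07, and Plagl1 fell by 4.68 ± 0.17. Primitive endoderm markers rose in 13 of 19 cases and fell in 2 (median 2.04, camera adjusted p = 0.0187, adjusted p = 0.43 with an estimated correlation). Lamb1, Col4a1 and Dab2 rose by 2.32 ± 0.11, 2.40 ± 0.16 and 2.92 ± 0.20 and Sparc fell by 1.40 ± 0.08. Other steep rises were those of Bcl11a (7.14 ± 0.24), Enpp2, which makes lysophosphatidic acid (6.97 ± 0.28), Vrtn (6.85 ± 0.14), Dll1 (6.74 ± 0.18) and Fndc3c1 (6.37 ± 0.26). Zfp608 rose to 30.3 ± 3.3 CPM in D3 EPL, 1800 times D3 ground with a counting interval of 323 to 71200. The steepest falls included Dmgdh (-8.18 ± 0.15) and Aox3 (-7.38 ± 0.24), and several genes were nearly without counts in EPL. Pglyrp1 was at least 151-fold lower in A2 EPL than in A2 ground, and Tlx2 at least 151-fold lower in D3. Ly6a was 6490 times higher in D3 ground than in D3 EPL (counting interval 1160 to 256000), Bhmt 804 times (222 to 6640), Aspa 448 times (80.4 to 17700), and Cdx1 in A2 354 times (121 to 1720). T fell by 2.87 ± 0.30. In total 10981 genes were called, 5485 higher and 5496 lower, 4113 of them by at least 2-fold (2481 higher and 1632 lower). Total-count scaling gave 6191 higher and 4808 lower.

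EPL and naive cells, neither of which had the inhibitors, differed in LIF and proline. All 15 LIF- and STAT3-responsive genes were lower in EPL (median -0.72, camera adjusted p = 3.27e-18, adjusted p = 9.12e-05 with an estimated correlation). So were 19 of 20 naive pluripotency factors, with 0 higher (median -0.86, camera adjusted p = 5.37e-33, adjusted p = 9.12e-05 with an estimated correlation). Klf4 fell from 199.7 ± 9.7 to 58.9 ± 7.0 CPM in A2 and from 169 ± 7.7 to 39.5 ± 5.1 CPM in D3 (-1.93 ± 0.07, edgeR adjusted p = 8.42e-15). Tbx3 fell by 2.68 ± 0.06. Formative genes rose in 13 of 14 cases and fell in 1 (median 1.47, camera adjusted p = 4.3e-29, adjusted p = 8.06e-07 with an estimated correlation). Pou3f1 rose by 2.67 ± 0.10, Sall2 by 2.39 ± 0.08, Otx2 by 1.92 ± 0.07, Dnmt3b by 1.63 ± 0.06 and Fgf5 by 3.97 ± 0.22.

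Among the primed genes, markers of EpiSCs, 8 of 16 rose and 3 fell (median 0.69, camera adjusted p = 0.000633, adjusted p = 0.00768 with an estimated correlation). Cldn6 rose by 1.58 ± 0.09, Car4 by 2.06 ± 0.15 and Zic5 by 0.79 ± 0.08. Genes of the ATF4 and amino acid response fell in 15 of 23 cases and rose in 1, or 15 and 2 adjusted over the list alone (median -0.26, camera adjusted p = 2.49e-07, adjusted p = 0.0219 with an estimated correlation). Atf5 fell by 1.80 ± 0.06, Nupr1 by 1.60 ± 0.14, Cth by 1.23 ± 0.05 and asparagine synthetase Asns by 0.90 ± 0.06. Proline transport and metabolism as a list was not called (5 higher and 6 lower of 16, median 0.00, camera adjusted p = 0.657; its mean and its test lay on the negative side). Within it the proline-synthesis enzymes Aldh18a1 and Pycr1 fell by 0.63 ± 0.04 and 0.76 ± 0.09, and Slc38a2, an amino acid transporter induced by amino acid shortage, rose by 0.83 ± 0.07.

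Targets of BMP signalling fell in 7 of 12 cases and rose in 2 (median -0.62, camera adjusted p = 0.0052, adjusted p = 0.0668 with an estimated correlation). Id3 fell by 1.06 ± 0.09, Smad6 by 1.30 ± 0.12, Smad7 by 0.90 ± 0.08 and the ligand gene Bmp4 by 0.70 ± 0.06. Cholesterol biosynthesis genes rose in 17 of 22 cases and fell in 0, or 19 and 0 adjusted over the list alone (median 0.49, camera adjusted p = 1.98e-06, adjusted p = 0.392 with an estimated correlation). Among them Cyp51 rose by 0.80 ± 0.10. Nuclear genes of the respiratory chain fell in 47 of 98 cases and rose in 3 (median -0.19, camera adjusted p = 0.00299, adjusted p = 0.88 with an estimated correlation). Ndufb8 fell by 0.72 ± 0.10 and Cox5a by 0.48 ± 0.08. Epithelial-mesenchymal transition genes had 9 higher and 4 lower of 17, or 10 and 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.00367, adjusted p = 0.0744 with an estimated correlation). Esrp1 (1.49 ± 0.06), Cldn7 (2.05 ± 0.16) and Epcam (0.77 ± 0.06) rose together with N-cadherin Cdh2 (1.36 ± 0.14). In the DNA methylation list 6 of 12 rose and 3 fell, or 7 and 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.00487, adjusted p = 0.245 with an estimated correlation). Tet2, which oxidises methylcytosine, fell from 183 ± 23 to 104 ± 22 CPM in A2 and from 166 ± 57 to 73.2 ± 9.9 CPM in D3.

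Nanog fell by 0.89 ± 0.06, Esrrb by 0.84 ± 0.08, Zfp42 by 0.68 ± 0.06, Tfcp2l1 by 1.22 ± 0.09, Pou5f1 by 0.28 ± 0.07 and Sox2 by 0.19 ± 0.05 between naive and EPL. In A2 alone the calls of Pou5f1 (-0.19), Sox2 (-0.09) and Zfp42 (-0.26, adjusted p = 0.0548) were lost. T, at 0.482 ± 0.22 CPM in A2 naive and 0.229 ± 0.20 CPM in A2 EPL, was called at -1.05 ± 0.38 (adjusted p = 0.0242). This call was lost in each line alone and in 5 of the 12 fits that left out 1 library. Steep rises besides that of Fgf5 were those of Mmp25 (3.19 ± 0.11), Kif1a (3.15 ± 0.20), Zfp608 (3.14 ± 0.16), Enpp2 (2.83 ± 0.18), Sema6a (2.78 ± 0.13) and Vrtn (2.74 ± 0.09). Steep falls besides that of Tbx3 were those of Dglucy (-3.19 ± 0.13), the activin B subunit gene Inhbb (-2.98 ± 0.12), Lonrf2 (-2.95 ± 0.16), Myo1f (-2.88 ± 0.11), Adgrd1 (-2.77 ± 0.13), Catip (-2.74 ± 0.22) and Gsta3 (-2.65 ± 0.14). In total 8489 genes were called, 4493 higher and 3996 lower, 1622 of them by at least 2-fold (787 higher and 835 lower).

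EpiSC libraries held transcripts typical of fibroblasts at levels far above those of EPL cells. Col1a1, the main fibrillar collagen gene (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), was at 1232 ± 163 CPM in EpiSC and 0.620 ± 0.23 CPM in EPL (10.94 ± 0.18, edgeR adjusted p = 1.35e-21). Tagln, a smooth muscle and myofibroblast gene, was at 335 ± 97 and 3.94 ± 0.38 CPM. All 18 fibroblast markers were higher, with a median log2 change of 7.74, or 6.94 with the 6 members that had no count in EPL at their bound (camera adjusted p = 1.11e-41, adjusted p = 0.000112 with an estimated correlation). RNA of the Y chromosome was scarce in EpiSC, where Eif2s3y lay at 1.01 ± 0.20 CPM against 28.4 ± 3.1 CPM in EPL (-4.79 ± 0.15). Xist was at 36.6 ± 10 against 4.69 ± 1.2 CPM (2.96 ± 0.32). Eif2s3y, Uty and Ddx3y kept 3.58%, 3.56% and 5.86% of their A2 EPL level in EpiSC, while Pou5f1, Sox2 and Nanog kept 45.6%, 50.2% and 93.2%. These levels belong to the same libraries as every gene group of the 3 EpiSC comparisons. For the changes in these comparisons, stage, a possible admixture of other cells and a possible origin other than A2 can therefore not be separated.

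**Figure D3:**
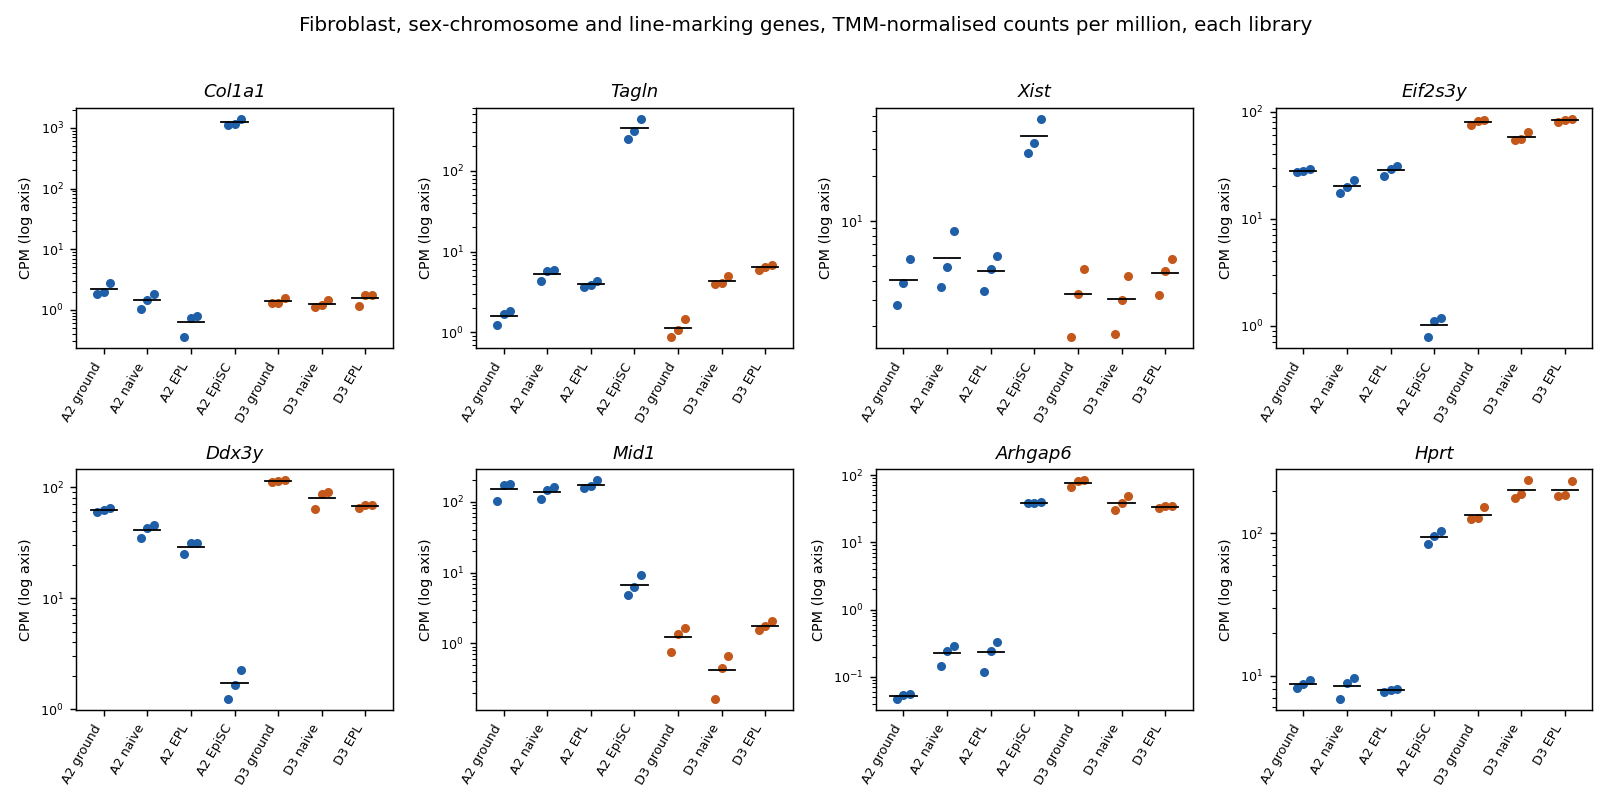
CPM (log axis) of Col1a1, Tagln, Xist, Eif2s3y, Ddx3y, Mid1, Arhgap6 and Hprt in the 4 stages, with A2 in blue and D3 in orange, 1 point per library and a line at each mean of 3. In A2 EpiSC, Hprt lay at 94.6 CPM, against 7.88 CPM in A2 EPL and 202 CPM in D3 EPL.

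Between EPL and EpiSC the general pluripotency factors fell in 14 of 15 cases with 0 higher (median -1.15, camera adjusted p = 1.19e-10, adjusted p = 0.0338 with an estimated correlation). Foxd3 fell by 2.73 ± 0.14, Lin28a by 2.22 ± 0.08, Trim28 by 1.31 ± 0.08, Dppa4 by 1.23 ± 0.08, Pou5f1 by 1.13 ± 0.10 and Sox2 by 0.99 ± 0.07. Nanog was not called (-0.10 ± 0.08, adjusted p = 0.286). Without EpiSC replicate 2, Nanog was called at -0.23 (adjusted p = 0.0171), and with total-count scaling its value was 0.10. Of the primed genes 11 of 16 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 2.15, camera adjusted p = 0.00104, adjusted p = 0.0184 with an estimated correlation). Fgf8 rose by 4.08 ± 0.30, Eomes by 3.23 ± 0.18, and Krt18 by 2.39 ± 0.21. T, a factor of the primitive streak, rose from 0.229 ± 0.20 to 4.41 ± 0.38 CPM. Formative genes moved the other way, 4 higher and 7 lower of 14 (median -0.52, camera adjusted p = 0.000312, adjusted p = 0.0184 with an estimated correlation). Dnmt3b fell by 3.13 ± 0.09, Grhl2 by 2.26 ± 0.09, Otx2 by 2.16 ± 0.11 and Pou3f1 by 1.71 ± 0.13, while Fgf5 rose 2.83-fold.

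Primitive endoderm markers rose in 18 of 19 cases and fell in 1 (median 3.04, camera adjusted p = 3.77e-07, adjusted p = 0.0338 with an estimated correlation). Those named by rule, Sparc (2.61 ± 0.12), Col4a1 (4.09 ± 0.22), Col4a2 (4.74 ± 0.26) and Pdgfra (4.25 ± 0.24), are also expressed by fibroblasts. Mesendoderm markers rose in 10 of 15 cases and fell in 2 (median 2.69, camera adjusted p = 0.0116, adjusted p = 0.161 with an estimated correlation), with Cyp26a1, which degrades retinoic acid, up by 5.32 ± 0.30. Trophectoderm markers were not called as a list (7 higher and 2 lower of 12, median 2.22, camera adjusted p = 0.0812). Naive pluripotency factors had 6 higher and 14 lower of 20 (median -0.95, camera adjusted p = 0.00373, adjusted p = 0.225 with an estimated correlation). Nr0b1 fell by 2.89 ± 0.14, threonine dehydrogenase Tdh by 2.86 ± 0.09, Zfp42 by 1.46 ± 0.09, Tfcp2l1 by 1.24 ± 0.13 and Esrrb by 0.94 ± 0.11. Klf4 rose by 1.26 ± 0.10, and Spp1 and Tbx3 rose from 173 ± 13 to 692 ± 19 CPM and from 21.2 ± 0.99 to 84.7 ± 5.6 CPM. Whether these rises came from the EpiSCs or from other cells in the libraries was not tested.

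All 12 genes of the 2-cell-like list rose (median 2.71, camera adjusted p = 0.0011, adjusted p = 0.324 with an estimated correlation), Tmem92 by 4.34 ± 0.28 and the paralog-rich Zscan4d 12.1-fold. Germline genes rose in 13 of 20 cases and fell in 2 (median 0.71, camera adjusted p = 0.005, adjusted p = 0.21 with an estimated correlation). Dazl was at 127 ± 11 against 6.76 ± 1.8 CPM and Asz1 at 11.3 ± 0.69 against 0.136 ± 0.067 CPM. Of the DNA methylation genes 4 of 12 rose and 8 fell (median -0.51, camera adjusted p = 0.0189, adjusted p = 0.324 with an estimated correlation), Dnmt3l by 2.85 ± 0.09. ATF4 and amino acid response genes had 8 higher and 14 lower of 23 (median -0.74, camera adjusted p = 0.00776, adjusted p = 0.225 with an estimated correlation). Atf4 fell by 1.68 ± 0.07 and Psat1 by 1.37 ± 0.08, and Atf5 rose by 1.81 ± 0.08.

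Cytosolic ribosomal protein genes fell in 76 of 79 cases with 0 higher, or 77 adjusted over the list alone (median -0.64, camera adjusted p = 3.09e-08, adjusted p = 0.497 with an estimated correlation). Among them were Rpl7 (-1.16 ± 0.11) and Rpl37a (-1.09 ± 0.13). Glycolysis genes fell in 15 of 21 cases and rose in 4, or 16 and 4 adjusted over the list alone (median -0.92, camera adjusted p = 0.005, adjusted p = 0.497 with an estimated correlation). Eno1 and Gapdh fell by 1.41 ± 0.11 and 0.99 ± 0.08, and the isoform Eno2 rose by 1.94 ± 0.18. Nuclear respiratory chain genes fell in 51 of 98 cases and rose in 6, or 50 and 6 adjusted over the list alone (median -0.30, camera adjusted p = 0.00373, adjusted p = 0.744 with an estimated correlation). Ndufs1 fell by 0.62 ± 0.06. Y-linked and X-inactivation genes had 2 higher and 5 lower of 7 (median -4.08, camera adjusted p = 0.000259, adjusted p = 0.101 with an estimated correlation). Uty and Ddx3y fell by 4.78 ± 0.26 and 4.08 ± 0.18.

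The steepest rises were in genes absent or nearly absent from EPL. Col3a1 was at least 4820-fold higher in EpiSC, Prrx1 at least 861-fold, Ccl2 at least 786-fold, Col8a1 at least 742-fold, Postn at least 517-fold, Tm4sf1 at least 457-fold and Pcdh7 at least 428-fold. The matrix protein gene Tnc reached 549 ± 198 CPM against 0.0986 ± 0.071 CPM. The steepest falls included Glod5 (-5.11 ± 0.32), Nlrp4a (-4.91 ± 0.22), the ubiquitin ligase gene Mid1 (-4.68 ± 0.23), Myt1 (-4.45 ± 0.26), Esrp1 (-4.31 ± 0.10) and Napsa (-4.25 ± 0.18). Mid1 and Myt1 also separate the lines, at 1.78 and 0.0934 CPM in D3 EPL, so their falls cannot be assigned to stage alone. In total 11667 genes were called, 6475 higher and 5192 lower, 4947 of them by at least 2-fold (3655 higher and 1292 lower). Scaling to the total count moved the median of all genes by 0.205 and split the calls into 7966 higher and 3638 lower.

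Both ends of the continuum, A2 ground state and EpiSC, differed in 12136 genes, 6488 higher and 5648 lower in EpiSC, 5579 of them by at least 2-fold (4099 higher and 1480 lower). Naive pluripotency factors fell in 19 of 20 cases and rose in 1 (median -1.62, camera adjusted p = 5.13e-14, adjusted p = 0.00435 with an estimated correlation). Tfcp2l1 went from 2266 ± 90 to 119 ± 12 CPM (-4.26 ± 0.15, edgeR adjusted p = 1.7e-16). Tdh fell by 3.48 ± 0.09, Nr0b1 by 2.87 ± 0.14, Esrrb by 2.12 ± 0.11, Zfp42 by 1.85 ± 0.09, Tbx3 by 1.75 ± 0.08 and Klf4 by 1.22 ± 0.10. Formative genes rose in 12 of 14 cases and fell in 2 (median 3.18, camera adjusted p = 3.23e-10, adjusted p = 0.000274 with an estimated correlation). Fgf5 rose by 6.85 ± 0.41, Fgf15 by 5.38 ± 0.23 and Pou3f1 by 5.13 ± 0.23. Sox11 rose by 4.27 ± 0.16, Sall2 by 3.20 ± 0.12, Otx2 by 3.17 ± 0.16 and Dnmt3a by 2.89 ± 0.08, whereas Dnmt3b fell by 0.87 ± 0.08. Primed genes rose in 13 of 16 cases and fell in 2, or 14 and 2 adjusted over the list alone (median 2.25, camera adjusted p = 6.65e-05, adjusted p = 0.00416 with an estimated correlation). Fgf8 rose by 5.38 ± 0.34, Cldn6 by 3.54 ± 0.15 and Zic5 by 1.88 ± 0.12, and T rose by 1.35 ± 0.27.

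LIF- and STAT3-responsive genes fell in 13 of 15 cases and rose in 2 (median -0.69, camera adjusted p = 3.11e-05, adjusted p = 0.0199 with an estimated correlation). Ly6g6e fell by 3.58 ± 0.16 and Junb rose by 1.67 ± 0.08. Primitive endoderm markers rose in 18 of 19 cases and fell in 1 (median 4.83, camera adjusted p = 1.59e-08, adjusted p = 0.0319 with an estimated correlation). They included Col4a2 (6.06 ± 0.28), Col4a1 (63.9-fold), Pdgfra (4.81 ± 0.25) and Lamb1 (3.56 ± 0.16). All 18 fibroblast markers rose here too (median 8.40, or 7.48 with the 4 members without a count in ground state at their bound; camera adjusted p = 2.92e-36, adjusted p = 0.000274 with an estimated correlation). Col1a2 was at 716 ± 97 against 0.201 ± 0.11 CPM. Of general pluripotency factors 3 of 15 rose and 10 fell (median -1.03, camera adjusted p = 0.000164, adjusted p = 0.176 with an estimated correlation). Foxd3 fell by 2.93 ± 0.14, Nanog by 1.62 ± 0.09, Sall4 by 1.33 ± 0.08, Pou5f1 by 1.22 ± 0.10 and Sox2 by 0.87 ± 0.07.

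ERK-responsive genes rose in 14 of 17 cases and fell in 3 (median 0.89, camera adjusted p = 0.000373, adjusted p = 0.0646 with an estimated correlation). Egr1 rose by 7.09 ± 0.27 and Dusp6 by 1.92 ± 0.07, while Etv5 fell by 1.78 ± 0.08. Imprinted genes had 15 higher and 6 lower of 25 (median 2.12, camera adjusted p = 4.75e-06, adjusted p = 0.0641 with an estimated correlation). H19 and the growth factor gene Igf2, neighbours under shared imprinted control, rose by 7.17 ± 0.25 and 7.16 ± 0.28, Cdkn1c by 6.26 ± 0.14 and Ndn by 2.61 ± 0.10. Neurectoderm markers had 11 higher and 2 lower of 13 (median 2.56, camera adjusted p = 0.000794, adjusted p = 0.0624 with an estimated correlation). Germline genes had 14 higher and 4 lower of 20 (median 2.04, camera adjusted p = 0.000794, adjusted p = 0.0988 with an estimated correlation), and 2-cell-like genes 12 higher and 0 lower of 12 (median 4.61, camera adjusted p = 6.65e-05, adjusted p = 0.183 with an estimated correlation). Ribosomal protein genes fell in 77 of 79 cases with 0 higher (median -0.72, camera adjusted p = 4.52e-08, adjusted p = 0.542 with an estimated correlation), and respiratory chain genes in 71 of 98 with 8 higher (median -0.53, camera adjusted p = 9.75e-05, adjusted p = 0.642 with an estimated correlation). ATF4 response genes fell in 13 of 23 cases and rose in 6 (median -0.30, camera adjusted p = 0.021, adjusted p = 0.238 with an estimated correlation). Y-linked and X-inactivation genes fell in 5 of 7 cases and rose in 1 (median -4.63, camera adjusted p = 0.000114, adjusted p = 0.0624 with an estimated correlation).

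Epithelial-mesenchymal transition genes, a list of both epithelial and mesenchymal genes, had 12 higher and 3 lower of 17. They were called at camera adjusted p = 0.037 (adjusted p = 0.176 with an estimated correlation), which gives no direction of the transition. The call was lost without A2 ground replicate 2 (0.06). Glycolysis genes, with 4 higher and 13 lower of 21, were called at camera adjusted p = 0.0389 (adjusted p = 0.651 with an estimated correlation). That call was lost without A2 ground replicate 3 or EpiSC replicate 3 (up to 0.205). Lox, which crosslinks collagen, was at least 2550-fold higher in EpiSC, Col6a1 at least 1290-fold, Gbp2b at least 641-fold and Lrrc32 at least 537-fold. The steepest falls were those of Trpm1 (-7.47 ± 0.25), Pglyrp1 (-6.39 ± 0.38), the Y-linked Uba1y (-6.35 ± 0.33), whose reads resemble those of its X-linked homologue, and Dmgdh (-6.15 ± 0.17). Aox3 fell 64.1-fold, and similar falls were those of Tlx2 (-5.90 ± 0.26), Bhmt2 (-5.87 ± 0.22) and Pla2g4e (-5.78 ± 0.24). With total-count scaling 8280 genes were higher and 3658 lower.

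Against naive A2 cells, EpiSCs had lower levels of all 15 general pluripotency factors (median -1.09, camera adjusted p = 1.59e-11, adjusted p = 0.0217 with an estimated correlation). Of the primed genes 14 of 16 were higher and 1 lower (median 2.93, camera adjusted p = 1.52e-06, adjusted p = 0.00114 with an estimated correlation). Pou5f1 fell from 1229 ± 103 to 489 ± 80 CPM (-1.33 ± 0.10, edgeR adjusted p = 1.73e-10). Foxd3 fell by 3.06 ± 0.14, Lin28a by 1.66 ± 0.08, Sall4 by 1.48 ± 0.08, Sox2 by 1.09 ± 0.07 and Nanog by 0.76 ± 0.08. Fgf8 rose by 4.73 ± 0.31, Cdh2 by 3.30 ± 0.19, Eomes by 3.20 ± 0.18 and T by 3.18 ± 0.33. Naive factors fell in 18 of 20 cases and rose in 1 (median -1.64, camera adjusted p = 5.29e-13, adjusted p = 0.0065 with an estimated correlation). Nr0b1 fell by 3.26 ± 0.14, Tdh by 2.91 ± 0.09, Tfcp2l1 by 2.55 ± 0.14, Zfp42 by 1.72 ± 0.09, Esrrb by 1.67 ± 0.11 and Klf4 by 0.50 ± 0.10. LIF- and STAT3-responsive genes fell in 12 of 15 cases and rose in 2 (median -1.22, camera adjusted p = 3.14e-06, adjusted p = 0.0101 with an estimated correlation).

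BMP targets fell in 9 of 12 cases and rose in 3 (median -0.70, camera adjusted p = 0.00626, adjusted p = 0.0613 with an estimated correlation). Bmp4 fell by 2.14 ± 0.09, Id1 by 2.05 ± 0.14, Id3 by 1.85 ± 0.13 and Id2 by 1.65 ± 0.11. Cholesterol genes rose in 18 of 22 cases and fell in 0, or 19 and 0 adjusted over the list alone (median 0.80, camera adjusted p = 0.00455, adjusted p = 0.518 with an estimated correlation). Cyp51 rose by 1.58 ± 0.14 and Hsd17b7 by 1.19 ± 0.10. Formative genes as a list were not called (9 higher and 4 lower of 14, median 0.77, camera adjusted p = 0.598). In it, Fgf5 (4.71 ± 0.32) and Pou3f1 (0.72 ± 0.14) were higher and Dnmt3b (-1.64 ± 0.08) and Otx2 (-0.59 ± 0.11) lower. All 18 fibroblast markers rose (median 8.35, or 7.12 with 4 members at their bound; camera adjusted p = 2.87e-41, adjusted p = 0.000103 with an estimated correlation). Postn was at least 586-fold higher and Dcn at least 450-fold. Mid1 (-4.35 ± 0.23), Cpsf4l (-4.20 ± 0.13), Napsa (-4.18 ± 0.18), Ubap1l (-4.12 ± 0.26) and Apol6 (-3.99 ± 0.23) fell. So did the Y-linked Ddx3y (-4.57 ± 0.18), Uty (-4.46 ± 0.26) and Eif2s3y (-4.29 ± 0.15), and Xist rose by 2.70 ± 0.31. Since Mid1 also separates the lines, at 0.429 CPM in D3 naive, its fall cannot be assigned to stage alone.

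Primitive endoderm markers rose in 16 of 19 cases and fell in 1 (median 3.26, camera adjusted p = 1.46e-06, adjusted p = 0.0613 with an estimated correlation). Genes of the 2-cell-like list rose in 11 of 12 cases and fell in 0 (median 2.62, camera adjusted p = 0.0028, adjusted p = 0.398 with an estimated correlation). Mesendoderm markers rose in 8 of 15 and fell in 3 (median 2.55, camera adjusted p = 0.0228, adjusted p = 0.175 with an estimated correlation). ATF4 response genes fell in 14 of 23 cases and rose in 7 (median -0.86, camera adjusted p = 5.24e-05, adjusted p = 0.0613 with an estimated correlation). Respiratory chain genes fell in 69 of 98 cases and rose in 5 (median -0.43, camera adjusted p = 7.61e-05, adjusted p = 0.577 with an estimated correlation). Ribosomal protein genes fell in 72 of 79 and rose in 1 (median -0.58, camera adjusted p = 6.73e-07, adjusted p = 0.567 with an estimated correlation). Y-linked and X-inactivation genes fell in 5 of 7 and rose in 1 (median -3.50, camera adjusted p = 0.00016, adjusted p = 0.0613 with an estimated correlation). Glycolysis genes fell in 11 of 21 cases and rose in 4 (camera adjusted p = 0.0205, adjusted p = 0.577 with an estimated correlation). Imprinted genes rose in 15 of 25 and fell in 8 (camera adjusted p = 0.0334, adjusted p = 0.424 with an estimated correlation). Both of these calls were also lost without EpiSC replicate 3, at adjusted p = 0.0532 and 0.0557. In total 11655 genes were called, 6476 higher and 5179 lower, 4877 of them by at least 2-fold (3536 higher and 1341 lower), and with total-count scaling 7838 were higher and 3854 lower.

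The lines D3 and A2, compared as the mean over ground, naive and EPL, differed in 6750 genes, 3313 higher and 3437 lower in D3, of which 622 differed at least 2-fold, 221 higher and 401 lower. At single stages 3325 genes differed in ground, 4959 in naive and 4880 in EPL cells. Among the genes named by rule, which leaves out pseudogenes, Arhgap6 and Mid1 on the X chromosome had the largest differences. Arhgap6 (ENSMUSG00000031355, chromosome X, 168795099 to 169304435) was at 77.1 ± 8.7 CPM in D3 ground and 0.0523 ± 0.0044 CPM in A2 ground, a ratio of 1480 with a counting interval of 507 to 7180. Mid1 (ENSMUSG00000035299, chromosome X, 169685199 to 170005736) was at 1.25 ± 0.45 CPM in D3 ground and 151 ± 43 CPM in A2 ground. Hprt, the purine salvage enzyme on chromosome X (ENSMUSG00000025630, 52988137 to 53021659), was 21.1-fold higher in D3 (4.40 ± 0.08, edgeR adjusted p = 4.14e-21). Other genes higher in D3 were Htatip2 (2.58 ± 0.09), the ferritin gene Ftl1 (2.25 ± 0.08), which shares reads with pseudogenes, Acan (2.21 ± 0.14), Vegfd (1.98 ± 0.09) and Zfp658 (1.70 ± 0.11). Lower in D3 were Atp2b4 (-1.80 ± 0.11), Inhbb (-1.79 ± 0.10), Fgf17 (-1.61 ± 0.06), Fam169b (-1.61 ± 0.09), Hr (-1.54 ± 0.07), the germline gene Piwil2 (-1.52 ± 0.08) and Ptk2b (-1.41 ± 0.09).

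Y-linked and X-inactivation genes were higher in D3 in 6 of 7 cases with 0 lower (median 1.26, camera adjusted p = 8.34e-11, adjusted p = 0.00933 with an estimated correlation). Zfy1 was higher by 2.49 ± 0.20, Kdm5d by 2.00 ± 0.28, Eif2s3y by 1.54 ± 0.06, Uty by 1.25 ± 0.09, Ddx3y by 1.01 ± 0.07 and Tsix by 0.62 ± 0.13. Xist was not called (-0.42 ± 0.21, adjusted p = 0.123), and Tsix and Xist overlap on opposite strands. Without the filter on low counts Xist was called at the same size (edgeR adjusted p = 0.000299). Formative genes were higher in D3 in 9 of 14 cases and lower in 2 (median 0.59, camera adjusted p = 1.2e-05, adjusted p = 0.00933 with an estimated correlation). Zic2 and Sall2 were 2-fold higher, Otx2 was higher by 1.10 ± 0.08, Pou3f1 by 0.83 ± 0.14, Dnmt3a by 0.63 ± 0.04 and Dnmt3b by 0.55 ± 0.05. Fgf5 was not called (0.37 ± 1.11, adjusted p = 0.826) and T was not called (0.11 ± 0.28, adjusted p = 0.798). The mean for Fgf5 includes ground cells, with 1 count in D3, while its EPL level given above was higher in D3 than in A2.

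Naive factors were lower in D3 in 14 of 20 cases and higher in 2, or 14 and 3 adjusted over the list alone (median -0.35, camera adjusted p = 3.22e-05, adjusted p = 0.106 with an estimated correlation). Tfcp2l1 was lower at -1.07 ± 0.08, Klf5 at -0.94 ± 0.06, Pecam1 at -0.69 ± 0.04, Mras at -0.60 ± 0.06, Klf4 at -0.37 ± 0.06, Zfp42 at -0.33 ± 0.05 and Esrrb at -0.27 ± 0.06. General pluripotency factors were not called (2 higher and 3 lower of 15, median 0.00, camera adjusted p = 0.768). Nanog (-0.37 ± 0.05) and Sox2 (-0.24 ± 0.04) were lower, and Pou5f1 was not called (0.05 ± 0.06, adjusted p = 0.558). Primed genes had 8 higher and 2 lower of 16 (median 0.39, camera adjusted p = 0.0393, adjusted p = 0.106 with an estimated correlation). Lefty2 (1.15 ± 0.14) and Zic5 (0.84 ± 0.07) were higher. LIF- and STAT3-responsive genes had 1 higher and 10 lower of 15 (median -0.30, camera adjusted p = 0.000307, adjusted p = 0.0725 with an estimated correlation). Germline genes had 1 higher and 11 lower of 20, or 2 and 12 adjusted over the list alone (median -0.35, camera adjusted p = 0.000552, adjusted p = 0.106 with an estimated correlation). Tex19.1 (-0.89 ± 0.07) and Mael (-0.88 ± 0.08) were among them.

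Cholesterol genes had 15 higher and 1 lower of 22 (median 0.25, camera adjusted p = 0.00216, adjusted p = 0.642 with an estimated correlation), with Mvd at 0.70 ± 0.07. Epithelial-mesenchymal transition genes had 9 higher and 3 lower of 17 (median 0.38, camera adjusted p = 0.0262, adjusted p = 0.154 with an estimated correlation), with Ocln (1.04 ± 0.09) and E-cadherin Cdh1 (0.62 ± 0.04) higher. ERK-responsive genes had 1 higher and 6 lower of 17 (median -0.06, camera adjusted p = 0.0488, adjusted p = 0.28 with an estimated correlation). Spry2 (-0.72 ± 0.03) and Spred1 (-0.57 ± 0.05) were lower, and the list's call was lost in 7 of the 18 fits without 1 library. Fibroblast markers were not called (2 higher and 1 lower of 18, or 1 and 1 adjusted over the list alone, camera adjusted p = 0.785). Imprinted genes had 9 higher and 4 lower of 25, or 10 and 5 adjusted over the list alone (median 0.16, camera adjusted p = 0.00196, adjusted p = 0.259 with an estimated correlation). Called higher were Plagl1 (2.20 ± 0.16), Nnat (2.07 ± 0.14), Ndn (0.98 ± 0.06), Mcts2 (0.77 ± 0.06), Mest (0.71 ± 0.06), Snrpn (0.66 ± 0.05), Impact (0.61 ± 0.05), H19 (0.54 ± 0.21) and Zrsr1 (0.41 ± 0.07). Called lower were Grb10 (-0.97 ± 0.06), Cdkn1c (-0.34 ± 0.08), Rtl1 (-0.32 ± 0.12) and Igf2r (-0.22 ± 0.09). The calls of H19, Rtl1 and Igf2r were lost in 12, 11 and 14 of the 18 fits without 1 library, and those of H19 and Igf2r also with total-count scaling (adjusted p = 0.0519 and 0.0556).

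Stage effects ran alike in both lines for most genes called in both. Across genes, which are not independent replicates, Pearson's r between the A2 and D3 log2 changes was 0.839 for naive against ground, 0.853 for EPL against ground and 0.566 for EPL against naive (Spearman's rho 0.826, 0.801 and 0.576). Of the 6781, 7230 and 3661 genes called in both lines, 99.42%, 97.73% and 94.92% changed in the same direction. A test of line by stage interaction called 2822 genes, 17% of those tested. The step from ground to naive differed between lines for 508 genes, ground to EPL for 2206 and naive to EPL for 2106. Between naive and EPL 5440 genes were called in A2 and 7439 in D3.

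Along the axis from the A2 ground mean (0) to the A2 EpiSC mean (1), over the 12136 genes called between them, A2 naive libraries lay at 0.301 ± 0.014 and A2 EPL libraries at 0.341 ± 0.011. The EpiSC end of this axis was set by the libraries with fibroblast transcripts and low Y-linked RNA, so a position on it is not a measure of stage alone. Of 26 genes off the Y that differed over 4-fold between the lines at all 3 stages, 20 lay on the D3 side of the midpoint in EpiSC. Line differences can therefore enter the axis, and a difference between D3 and A2 on it is not one of stage alone. D3 libraries, which had no part in setting the axis, lay at 0.0133 ± 0.018 in ground, 0.314 ± 0.0074 in naive and 0.463 ± 0.0082 in EPL. The D3 EPL mean exceeded the D3 naive mean by 0.148 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give), with no overlap between libraries. In A2 the same difference was 0.0404 (exact permutation p = 0.1), and D3 EPL exceeded A2 EPL by 0.121 (exact permutation p = 0.1). D3 naive exceeded D3 ground by 0.301 (exact permutation p = 0.1). D3 and A2 differed by 0.0135 in naive and 0.0133 in ground cells (exact permutation p = 0.2 and 0.3). The A2 ground libraries themselves set the 0 of the axis, so the p-value for ground cells cannot judge that difference. These 6 differences were each tested once, and none can pass 0.05 with 3 libraries per group.

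**Figure D4:**
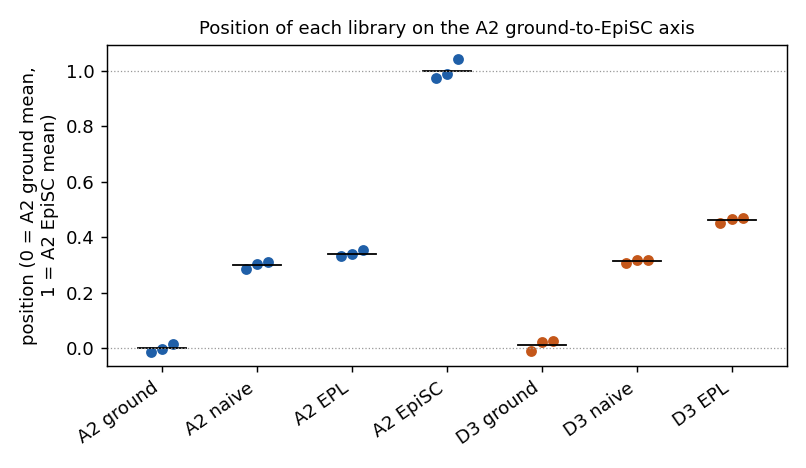
Position of each library on the axis from the A2 ground mean (0) to the A2 EpiSC mean (1), by group, with 1 point per library and a line at the mean of 3. A2 naive and EPL lie at 0.301 and 0.341, D3 naive and EPL at 0.314 and 0.463. The EpiSC libraries that set 1 end carry fibroblast transcripts.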

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

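Differences between the lines were tested with terms planned in advance. For the EpiSC libraries, the tests of fibroblast markers, of dilution and of line-marking genes were chosen only after the results had been seen, while leaving out library 3 and the tests of length, GC content and scaling were written before.

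The EpiSC libraries carried fibroblast transcripts, and 18 of 18 fibroblast markers were higher than in EPL by over 1 on the log2 scale, the smallest by 1.62. RNA of fibroblast-like cells in these cultures is a hypothesis that fits this result, and since the test was chosen after it, the result cannot test the hypothesis. Dilution by cells without any of the general pluripotency factors would lower all of these factors alike. The falls were uneven, with 6 of 15 factors over 3 SE from the median change of -1.15, 3 below and 3 above, within -2.73 to -0.102. Cells that express some of the factors would also give uneven falls, and this test too was chosen after the values had been seen. It therefore cannot decide whether dilution was the whole cause. Library 3 alone does not account for the transcripts, since 18 markers were still called without it, although its markers had a median 0.357 above the mean of libraries 1 and 2, with 15 above both. Stage and admixture cannot be separated here, since EpiSC is a single group of A2.

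Y-linked RNA was low in EpiSC libraries, with a median change of -4.59 over 5 genes against EPL, and genes that mark the lines were shifted. Relative to the median of the general pluripotency factors, this median was -3.44. Dilution of A2 RNA by cells without a Y chromosome and without these factors would lower both sets alike. It is argued against as the whole cause for the Y-linked genes, since the factors had a median of -1.15 and a lowest value of -2.73. Dilution by cells with these factors and no Y chromosome would give -3.44 too and is left open. Loss of the Y chromosome alone is argued against by the 16 genes off the Y with higher levels in A2, whose median change was -2.7 (-1.54 relative to the same factors). Of 26 line-marking genes off the Y, 20 lay on the D3 side of the midpoint in EpiSC, where 2.56 were expected from genes matched on level. At most a share of 1e-04 of 10000 random draws reached that number, but the draws treated the genes as independent. Of the 13 line-marking genes that are not pseudogenes, 10 lay on the D3 side, where 0.555 were expected. EpiSC cells of another origin than A2, such as host embryo cells, remain an open hypothesis, since related genes share reads or neighbours, are not independent, and a strain variant was not tested.

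The change from naive to EPL along the axis was 0.148 in D3 and 0.0404 in A2, an excess of 0.108. Length bias is argued against by an excess of at least 0.0784 in each of 3 classes of exon length (highest 0.133), GC bias by at least 0.0878 in each of 3 classes of GC content (highest 0.127), and library scaling by 0.105 and 0.112 with the other scalings. Exchanging line labels within stages gave an excess as large in 38 of 400 relabelings, but this share cannot judge the excess, since naive libraries of the lines nearly coincide and every relabeling that keeps the EPL libraries apart by line gives a similar value. A stronger response of the D3 line is left as a hypothesis.

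The number of called genes was compared with that after regrouping the libraries. For naive against ground, EPL against ground and EPL against naive, 10518, 10981 and 8489 genes were called, and the highest among the other groupings was 6900, 7159 and 5180, so that the real one was the only 1 of 100 to reach its count. The highest values came from groupings that keep 1 line intact, and those that keep neither gave at most 0. For D3 against A2 the count was 6750 and the highest other 682, and for the interaction 2822 and 969, again 1 of 100. For EpiSC against EPL, ground and naive the counts were 11667, 12136 and 11655, with highest other counts of 1, 0 and 0, and the 10 splits are too few to judge. In all these comparisons a regrouping mixes stages or lines within a group, which adds their differences to the spread and lowers the count. The lower counts of the other groupings can therefore not judge chance.

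The following named genes differed in their stage effect between lines by a test of the difference itself, and the values are D3 minus A2 on the log2 scale. A negative value can arise from a smaller rise in D3, as for Otx2 from ground to EPL (5.33 in A2, 3.95 in D3). It can also arise from a larger fall, as for Nanog (-1.52 in A2, -2.21 in D3). A positive value can arise from a larger rise or a smaller fall in D3. In naive against ground the genes were Trpm1 (-2.84), Otx2 (-2.07), Pecam1 (-1.18), Tbx3 (-0.424), Snrpn (0.561), Lamb1 (0.805) and Axin2 (1.07). In EPL against ground the value was negative for Ly6a (-4.45), Otx2 (-1.39), Pecam1 (-1.21), Dnmt3l (-0.984) and Spp1 (-0.82). It was also negative for Nanog (-0.697), Bcl3 (-0.68), Zfp42 (-0.56), Myc (-0.478) and Sox2 (-0.309). It was positive for Dusp6 (0.467), Snrpn (0.652), Uhrf2 (0.694), Lamb1 (1.24), Cldn7 (1.27), Vrtn (1.53), Dab2 (2.05), Zfp608 (4.15) and Fgf5 (4.69). The values of Ly6a, Zfp608 and Fgf5 rest on 1 count in a D3 group. In EPL against naive the value was negative for 16 genes, all of which fell in both lines and fell more in D3. These were Adgrd1 (-1.6), Nupr1 (-1.24), Inhbb (-1.2), Myo1f (-1.16), Spp1 (-1.14), Bcl3 (-0.938), Id3 (-0.934), Gsta3 (-0.916) and Bmp4 (-0.898). The remaining ones were Zfp42 (-0.838), Mras (-0.794), Cth (-0.75), Atf5 (-0.684), Asns (-0.492), Nanog (-0.468) and Aldh18a1 (-0.445). The value was positive for Uhrf2 (0.578), Cldn6 (0.643), Otx2 (0.688), Sall2 (0.823), Sema6a (0.976), Mmp25 (0.99), Fndc3c1 (1.35), Zfp608 (1.42) and Kif1a (1.54). These genes rose more in D3, while Smad7 (0.807) fell less there.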

How the results depend on the processing

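The tests without EpiSC libraries and without genes over 10-fold higher in EpiSC were chosen only after the results had been seen, and all others were planned. Of 7907 repeats of the 409 results of named genes, 7803 kept direction and call, 53 lost the call, 27 gained it and 24 turned direction. Against a fold change of 1.5, fewer genes were called because a larger change is asked for: 4008 in naive against ground, 4746 in EPL against ground, 1557 in EPL against naive, 5802, 6541 and 5732 in EpiSC against EPL, ground and naive, and 559 in D3 against A2. EPL against naive in A2 alone gave 5363 genes, where the A2 difference in the fit of all libraries gave 5440. All other counts of called genes, among them 6861 for EPL against naive in D3 alone, stayed within 1.5 times. With an estimated correlation 29 of 87 list calls were kept, and the lists called numbered 2, 4 and 5 in naive against ground, EPL against ground and EPL against naive, 5, 6 and 5 in EpiSC against EPL, ground and naive, and 2 in D3 against A2. With fry, which tests each list without the other genes, they numbered 22, 25 and 17, then 28 and 26 in EpiSC against EPL and naive, and 17 in D3 against A2. For the reversals below the cause was not tested, and none of these genes was called in the full fit.

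Zfp42 in naive against ground (0.0150) was at -0.127 in A2 alone and between -0.00768 and 0.0575 without single libraries. In EPL against ground, Pou5f1 (-0.0561) was at 0.00786 with total-count scaling, and Sox2 (-0.0340) at 0.0298 with it and at 0.123 in A2 alone. In D3 alone Sox2 was called at -0.193 (edgeR adjusted p = 0.0203). Nanog in EpiSC against EPL (-0.102) was at 0.103 with total-count scaling. In D3 against A2, Fgf5 (0.369) was between -0.241 and 0.656 and T (0.106) between -0.0382 and 0.418 without single libraries. Mirg (-0.00155) was at 0.000607 with RLE, 0.00666 without the filter, 0.00148 with DESeq2, 0.000545 without EpiSC libraries, and between -0.0582 and 0.0470 without single libraries.

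Same-numbered libraries of a line had residual correlations between -0.159 and 0.21 over 27 pairs, of which 3 were over 0.1, so the numbers were not taken to pair the samples. With a replicate block within lines, 10346 genes were called in naive against ground and 6512 in D3 against A2, 77 of 87 list calls were kept with 6 lists called in naive against ground, and Mirg in D3 against A2 was at 0.00123. With this replicate block the calls of general and naive pluripotency factors, Wnt targets, DNA methylation genes and neurectoderm markers ended in naive against ground. So did those of DNA methylation and epithelial-mesenchymal transition genes in EPL against ground, DNA methylation genes in EPL against naive, and primed and ERK-responsive genes in D3 against A2. In D3 against A2 H19 was no longer called (0.540, adjusted p = 0.0595) and Zim1 was called (0.636, adjusted p = 0.0364) with the replicate block.

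In simulated data 49.3% of 1.5-fold interactions were recovered, and depth was not varied. Genes near 0 counts have no reliable fold.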

Other observations

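The genes in this part were picked after their values had been seen, and no tests beyond the planned ones were made. Some genes moved in opposite directions in the lines. Nipa1 fell in A2 (-1.01 ± 0.14) and rose in D3 (1.08 ± 0.18) from ground to naive (interaction adjusted p = 1.43e-05). From ground to EPL, Chrna4 fell in A2 (-3.43 ± 0.30) and rose in D3 (1.36 ± 0.35; interaction adjusted p = 4.97e-07), and Fcgrt rose in A2 (1.26 ± 0.20) and fell in D3 (-1.24 ± 0.17; interaction adjusted p = 1.38e-06).

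Genes of the Nodal and activin pathway were called higher in 7 of 11 cases and lower in 3 in EPL against ground, with a median log2 change of 0.738 and no call of the list (camera adjusted p = 0.0879). Mitochondrially encoded genes were lower in 20 of 27 cases and higher in 1 in EPL against ground, with a median of -0.57 and no call (camera adjusted p = 0.166). Heat shock genes in D3 against A2 were higher in 5 of 12 cases and lower in 2, with a median of 0.0963 and no call (camera adjusted p = 0.0579).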
